A study of Mus musculus with 24 samples.

How the data were processed

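The series holds RNA-seq data from 24 libraries of mouse pancreatic cancer cells, in 6 groups of 4 libraries. The groups combine 3 cell lines (the parental KPC line and the PAR-1 knockout lines KPC-Par1-KO1 and KPC-Par1-KO8, here KO1 and KO8) with 2 conditions, vehicle or thrombin at 1 U/mL for 24 h. The labels number the replicates but do not say whether they were separate cultures, so the p-values measure only the spread between these samples. The deposited values were raw counts per Ensembl gene, 1 library per file, with no normalization. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.32, aligned with TopHat2 to the mm10 mouse genome and counted with HTSeq 0.6.1. The TopHat2 version, the annotation release and the strand setting of the counting were not given in the sources used here. The kit marks strand, per the labels, but counts of genes that overlap a gene on the other strand are uncertain without that setting. Of the 340 genes named by the rule below, 19 shared at least 20% of their exon bases with another gene, among them Fosl1 (57.2%, with Ccdc85b), Sdr39u1 (48.4%, with Khnyn), Rarb (38.4%, with Top2b or Gm48162), Ccnd1 (23.4%), Dusp5 (22.1%) and Adora1 (20.1%). Klra2, Mcpt8, Ugt2b36, Selenbp2, H2-Q4, H2-Q10 and Serpinb1a belong to families of similar genes among which reads could be split, so their values are uncertain.

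Each file listed 48440 features, of which 48058 matched a gene symbol in the mouse reference table. The other 382 held 0.0412% of all counts. Total counts per library ran from 16219715 to 29951026, with a median of 24166493. Where a group had no counts for a gene, a floor of 3 counts over the group was used, so that the fold change is a lower bound. With 1 to 3 counts in a group, the ratio is given with its 95% counting interval. Intervals and floors of this kind cover counting error only.

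The counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes with low counts were removed with edgeR's default filter given the 6 groups, which left 15613 genes. Libraries were scaled by TMM factors, and edgeR's quasi-likelihood test was fitted to all 24 libraries with 1 mean per group, which left 18 residual degrees of freedom. The spread of a gene was thus pooled over the groups, so 1 library that stands apart widens its SE in every line. For Ptgs2 and Areg, KO8 vehicle library 3 was such a library. The common biological coefficient of variation was 6.18%. All adjusted p-values are Benjamini-Hochberg values, over the genes tested or over the gene lists tested, with a threshold of 0.05, and a second count took genes with an absolute log2 fold change of at least 1. Log2 fold changes used a prior count of 0.125, and CPM is the usual unit of counts scaled to the TMM-adjusted library size. A value after ± is an SE beside a log2 fold change and an SD over the 4 libraries beside a CPM.

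The tests covered 8 results. They were thrombin against vehicle in each of the 3 lines, the difference of that effect between KPC and each knockout line (an interaction contrast), each knockout line against KPC under vehicle, and KO1 against KO8 under vehicle. In all, 34 gene lists were written before the data were examined, as were the design, the alternatives and the rule for the genes named. Of these lists, 31 had enough genes past the filter to be tested with limma's camera, at its preset correlation of 0.01 between genes. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance in 1 direction without comparing them with other genes, served as alternatives. In the list results, "with an estimated correlation" refers to the former.

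The rule named 9 genes fixed in advance (F2r, F2rl1, F2rl2, F2rl3, F3, Kras, Trp53, Csf2 and Ptgs2), of which Csf2 and Ptgs2 were taken from later work on this system, so that their direction is not independent evidence. For thrombin in KPC it then named the 10 highest and 10 lowest log2 fold changes. For the knockout lines against KPC under vehicle it named the 10 highest and 10 lowest that passed in both lines with the same sign, ranked by the smaller of the 2 absolute values. For thrombin in KO1, thrombin in KO8, the differences (passing in both) and KO1 against KO8 it named the 5 highest and 5 lowest. All of these were genes past the threshold with a mean of at least 1 CPM over the libraries compared and a symbol that is not a clone, pseudogene or small RNA name. Except for the differences, the CPM of the 2 groups also could not overlap. Last, the rule took from each list and comparison up to 4 genes past the threshold by smallest adjusted p. Genes named outside this rule are said to have been chosen after their values were seen.

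The alternatives were RLE factors, scaling by total counts, no filter, a filter of 1 CPM in at least 4 libraries, DESeq2 1.42.0, edgeR's older quasi-likelihood method, the replicate number as a block, a fit to the groups compared only, and leaving out each library in turn. An alternative added after the data had been seen thinned all libraries to 16219715 counts. Overlaps of the comparisons that share the KPC vehicle libraries were set against simulated unchanged groups, against independent lists, and against fits with those libraries split between the comparisons. For each count of genes, other splits of the same libraries were fitted as well. Chromosome medians used 12499 genes on 20 chromosomes with an average log2 CPM of at least 1, with 95% bootstrap intervals. Data handling and plots used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

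The steps were tested on simulated counts drawn from the real means and library sizes. In each comparison 50 genes were changed per fold, all with a mean of at least 1 CPM. An adjusted p-value depends on how many genes change, so the shares hold for that setting and do not give the recovery in the real comparisons. For thrombin in KPC, 62% of the genes changed 1.25-fold, 94% of those changed 1.5-fold and 98% of those changed 2-fold were recovered, with 14873 genes tested. For KO1 the shares were 54%, 86% and 96% (14820 genes), and for KO8 they were 56%, 84% and 98% (15016 genes). For the difference between KPC and KO1 they were 24%, 72% and 98%, and for that between KPC and KO8 36%, 74% and 92%. Counts drawn from means hold no library that stands apart from its group, as a KO8 vehicle library did in the data. The shares for KO8 and for its difference from KPC therefore do not give the recovery in the real KO8 libraries. They cannot show that the absence of calls there means an absence of change.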

Results

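Gene expression was measured by RNA-seq of total RNA, depleted of ribosomal RNA, in cultured mouse pancreatic ductal adenocarcinoma cells. The parental line, KPC, was derived from C57BL/6 mice and carries mutant Kras and Trp53 alleles. KO1 and KO8, named KPC-Par1-KO1 and KPC-Par1-KO8 in the labels, are lines of these cells in which PAR-1, the thrombin receptor encoded by F2r, was targeted with CRISPR/Cas9. Cells of each line were kept in low serum for 24 h with vehicle or with 1 U/mL thrombin, the protease that activates PAR-1 by cleavage. There were 24 libraries, 4 in each of the 6 groups, with total counts between 16219715 and 29951026. The series title places the work in the study of the tissue factor and thrombin axis and of tumor cell PAR-1. Mitochondrial genes took 2.79 to 2.84% of the counts in the KPC vehicle libraries and 2.05 to 2.30% in the KPC thrombin libraries.

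The targeted gene was read first. F2r (ENSMUSG00000048376, mm10 chromosome 13, 95601803 to 95618487, minus strand) had 310.9 ± 13.8 CPM (counts scaled to library size) in KPC vehicle libraries (SD, n = 4), 206.6 ± 8.47 in KO1 and 163.3 ± 7.78 in KO8. Its log2 fold change against KPC was −0.59 ± 0.042 (SE) in KO1 and −0.93 ± 0.042 in KO8, with edgeR adjusted p of 6.22e-13 and 6.51e-17. F2r RNA was thus lower in both knockout lines but far from absent, with 3347 to 4997 counts in each of the 16 libraries. Genes of chromosome 13 as a whole were also lower in these lines, by a median of −0.67 in KO1 and −0.50 in KO8 relative to all genes. The edited positions were not given, and counts over the whole gene show neither the edit nor whether receptor protein was made. Of the other members of the family, F2rl1, which encodes PAR-2, had 71.8 ± 3.14 CPM in KPC vehicle libraries and did not pass in KO1 (log2 fold change −0.0085) or KO8 (−0.031). F2rl2 had at most 1 count in a library, and F2rl3, which encodes PAR-4, at most 3, so neither was detectable at this depth.

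**Figure D1:**
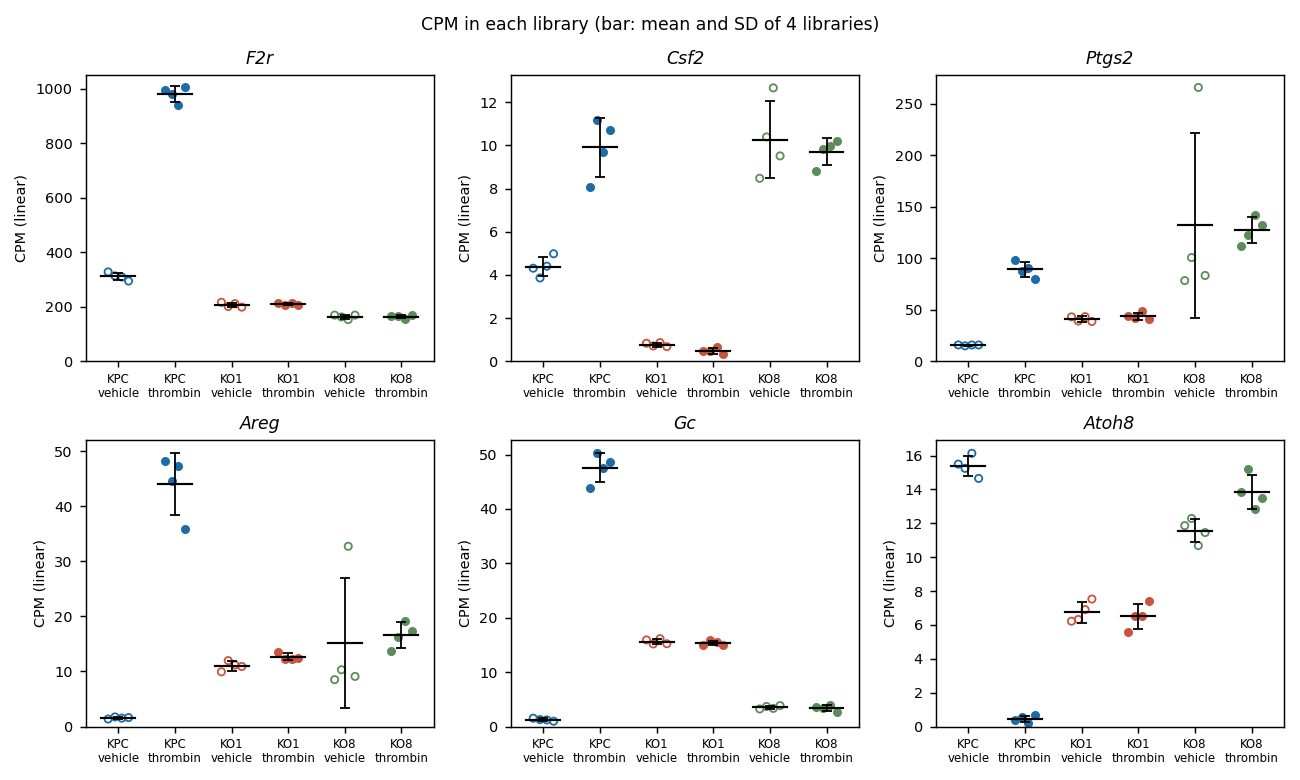
CPM (counts scaled to library size, linear axis from 0) of F2r, Csf2, Ptgs2, Areg, Gc and Atoh8 in each library, with points for libraries and bars for the mean ± SD of the 4 libraries of a group. F2r rose from 310.9 to 979.4 CPM with thrombin in KPC and stayed near 210 CPM in KO1 and 164 CPM in KO8, and Ptgs2 stood at 265.7 CPM in 1 KO8 vehicle library.

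In KPC cells, the first comparison asks what thrombin does where its receptor is intact. Growth factor and signalling genes were among those that rose. Wnt7b, a Wnt ligand, went from 0.0942 ± 0.071 to 6.61 ± 0.664 CPM (SD, n = 4), a log2 fold change of 6.12 ± 0.35 (SE), and Areg, a ligand of the EGF receptor, went from 1.57 ± 0.161 to 44.0 ± 5.63 CPM (4.80 ± 0.34). F2r itself rose 3.15-fold, to 979.4 ± 29.1 CPM (1.66 ± 0.042). Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis, rose from 15.6 ± 0.424 to 89.1 ± 7.34 CPM (2.51 ± 0.26), and Csf2, the cytokine GM-CSF, from 4.39 ± 0.461 to 9.90 ± 1.37 CPM (1.19 ± 0.12). Atoh8, a basic helix-loop-helix transcription factor, fell from 15.4 ± 0.614 to 0.449 ± 0.196 CPM (−5.01 ± 0.14), and Synm, an intermediate filament protein, from 22.6 ± 0.366 to 0.873 ± 0.116 CPM (−4.71 ± 0.13).

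The other largest rises, as log2 fold changes, were those of the synaptic vesicle protein gene Synpr (6.34), the serine protease gene Prss22 (5.68), the vitamin D binding protein gene Gc (5.24), the prokineticin receptor gene Prokr2 (4.99), Mcpt8 (4.91), the interleukin receptor subunit gene Il18rap (4.85) and Sh2d1b1 (4.78). Upk3b (−5.71), which encodes a uroplakin, Fhl1 (−5.61), Selenbp2 (−5.04), the sulfotransferase gene Sult1a1 (−4.94), Keg1 (−4.85), the glucuronosyltransferase gene Ugt2b36 (−4.83) and Smyd1 (−4.70) fell the most, beside Sh3tc2. Klra2 also rose, from 0.0642 to 2.23 CPM, with most of its few vehicle counts in library 3. Sh3tc2 had 3 counts in the thrombin libraries, a ratio of 69.5 with a counting interval of 23.8 to 337. Kras (0.88 ± 0.078), Trp53 (0.31 ± 0.07) and F2rl1 (0.26 ± 0.05) rose. F3, which encodes tissue factor, went from 62.3 to 56.0 CPM and did not pass (−0.15 ± 0.075, adjusted p = 0.0699), but it passed in 6 of 8 alternatives, with adjusted p between 0.00601 and 0.0426. In all, 10719 of the 15613 genes tested passed in edgeR's quasi-likelihood test, 5352 up and 5367 down, and 2524 of them changed at least 2-fold (1032 up, 1492 down). DESeq2 called 10756 genes.

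All 23 mitotic (G2/M) genes tested rose in KPC, including the spindle assembly factor Tpx2 (1.95), the checkpoint kinase Bub1 (1.78), cyclin B1, Ccnb1 (2.15), and Cdca8 (1.57), with a camera adjusted p of 3.02e-17 but adjusted p = 0.139 with an estimated correlation. Of 22 replication (G1/S) genes, 17 rose and 1, Ung, fell (−0.26), with Cdc45 at 1.28, cyclin E1, Ccne1, at 1.13 and the helicase subunit Mcm4 at 0.41 (0.0196, but adjusted p = 0.535 with an estimated correlation). Of 21 feedback targets of the MAP kinase pathway, 16 rose and 2 fell (1.02e-05, but adjusted p = 0.109 with an estimated correlation). The AP-1 factor gene Fosl1 rose by 3.35, the phosphatase gene Dusp5 by 2.40 and cyclin D1, Ccnd1, by 0.85, while the ephrin receptor gene Epha4 fell (−1.31). Glycolysis and hypoxia genes included 14 that rose and 4 that fell of 21 (0.0185, adjusted p = 0.356 with an estimated correlation). The glucose transporter gene Slc2a1 (1.41), Pfkp (1.37) and Hk2 (0.79), which act early in glycolysis, rose, and Ndrg1 fell (−1.68). Of 5 genes of the basal or squamous tumor subtype, 3 rose, among them Areg and Hmga2 (1.90), and 1 fell, the lineage factor Trp63 (0.0196, adjusted p = 0.139 with an estimated correlation). Trp63 had 2 counts in the thrombin libraries, both in library 1, a ratio of 43.6 with a counting interval of 12.1 to 360.

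The list of the integrated stress response and unfolded protein response moved in 2 directions in KPC. Of 20 genes, 10 rose and 7 fell, with a camera adjusted p of 4.4e-05, which held with an estimated correlation (adjusted p = 0.00277). Those that rose included the transcription factor gene Atf4 (2.10) and the amino acid synthesis genes Asns (2.84), Psat1 (2.67) and Shmt2 (1.79). Those that fell, chosen after their values were seen, included the transcription factor gene Xbp1 (−0.73) and the endoplasmic reticulum chaperone or folding genes Pdia6 (−0.44), Calr (−0.36) and Hspa5 (−0.27).

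Of 15 ductal markers, 13 fell and 2 rose after thrombin in KPC (camera adjusted p of 5e-04, with adjusted p = 0.0125 with an estimated correlation). Bicc1 (−1.80), the stem cell marker Prom1 (−1.45) and the ductal transcription factor Hnf1b (−1.28) fell, while Spp1, which encodes osteopontin, rose from 4576 to 11380 CPM (1.31). Of 17 epithelial junction genes, 11 fell and 3 rose (0.000164, adjusted p = 0.109 with an estimated correlation). The desmosome gene Dsp (−2.27), the tight junction gene Ocln (−1.71) and the epithelial factor Elf3 (−1.75) fell, and E-cadherin, Cdh1, went from 908.2 to 569.3 CPM (−0.67), while the keratin genes Krt18 (0.97) and Krt8 (0.67), named after their values were seen, rose. Interferon response genes fell for 16 of 24 members (17 when adjusted over the list alone) and rose for 2, with the RNA sensors Ddx58 (−1.35) and Ifih1 (−0.95) and the GTPase gene Gbp2 (−1.40) among them (0.0126, adjusted p = 0.111 with an estimated correlation). Of 22 cholesterol synthesis genes, 17 fell and none rose, including Insig1 (−1.16), Mvd (−1.13), Dhcr7 (−0.87) and Lss (−0.73), with a camera adjusted p of 0.0126 and adjusted p = 0.65 with an estimated correlation. Apart from the interferon list, the counts of these 10 lists were the same when adjusted over the list alone.

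**Figure D2:**
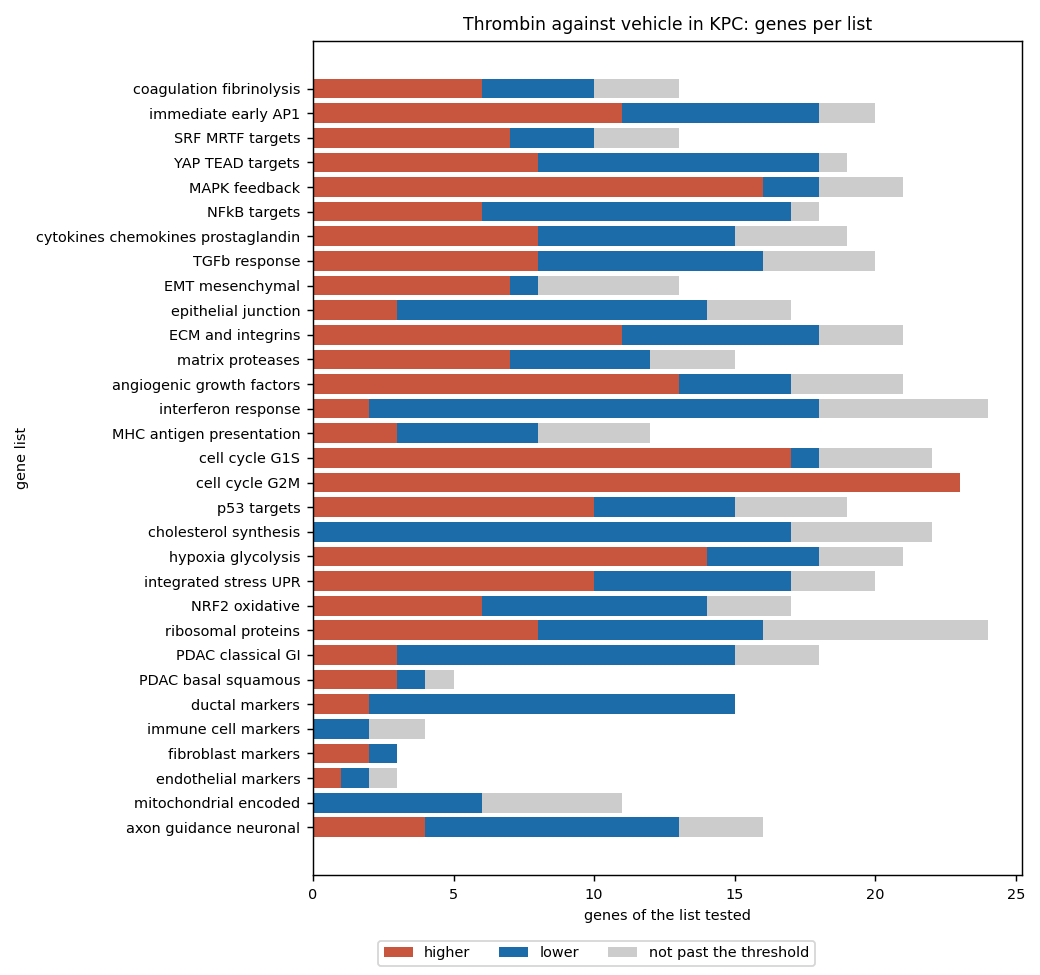
Number of genes (horizontal axis, stacked bars) that were higher, lower or not past the threshold after thrombin in KPC, for each of the 31 gene lists tested (vertical axis). All 23 G2/M genes were higher, 13 of 15 ductal markers were lower, and most lists held genes moving in both directions.

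The other 21 lists held changed genes but did not stand apart from other genes in KPC, with camera adjusted p from 0.0593 to 0.964. Among inflammatory lists, NF-kB targets had 6 up and 11 down of 18, such as Csf1 (−1.83) and Tnfaip2 (0.97). Cytokine, chemokine and prostaglandin genes had 8 up and 7 down of 19, with Ptgs1 (−3.48), Il33 (−2.24) and Cxcl15 (−4.09) against Ptgs2 and Csf2. Antigen presentation genes had 3 up and 5 down of 12, with Tap1 at −1.82 and H2-K1 at 0.80. Immediate early genes had 11 up and 7 down of 20 (8 down when adjusted over the list alone), with Egr1 at 2.17 and Btg2 at −1.40. Targets of SRF had 7 up and 3 down of 13 (Fhl2 1.09, Actg1 −0.63), targets of YAP 8 up and 10 down of 19 (11 down when adjusted over the list alone, Gadd45a 2.76, Rbms3 −2.59), and TGF-beta response genes 8 up and 8 down of 20 (Pmepa1 1.87, Tgfb3 −2.44). Targets of p53 had 10 up and 5 down of 19 (11 up when adjusted over the list alone), with Cdkn1a at 2.19 and Sesn2 at 2.47. NRF2 targets had 6 up and 8 down of 17, with the cystine transporter gene Slc7a11 at 2.71 and the glutathione transferase gene Gsta1 at −4.43.

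Among lists on the cell surroundings in KPC, coagulation and fibrinolysis genes had 6 up and 4 down of 13, with the plasminogen activator inhibitor gene Serpine1 at 2.81 against coagulation factor V, F5, at −1.84. Mesenchymal genes had 7 up and 1 down of 13 (Zeb2 1.53, Sparc −1.32), and matrix and integrin genes 11 up and 7 down of 21 (Fn1 0.94, Lamb3 −1.76). Matrix protease genes and their inhibitors had 7 up and 5 down of 15 (Mmp10 4.43, Timp3 −2.86), and axon guidance genes 4 up and 9 down of 16 (Nrp2 2.91, Nrp1 −1.82). Angiogenic growth factor genes had 13 up and 4 down of 21 (Pgf 2.01, Fgf1 −2.75), with a camera adjusted p of 0.0593 that passed without thrombin library 1 (0.0426) or 3 (0.0382). Genes of the classical tumor subtype had 3 up and 12 down of 18, with the galectin gene Lgals4 at −1.89 and Muc1 at −1.14 against Cdh17, which went from 319.3 to 1997 CPM (2.64). Ribosomal protein genes had 8 up and 8 down of 24 (Rpl10a 0.87, Rpl4 −0.33), and mitochondrially encoded genes 0 up and 6 down of 11 (mt-Nd1 −0.40, mt-Co1 −0.36). Of markers of other cell types, 4 immune (2 down, such as Ptprc), 3 fibroblast (2 up, 1 down, with Col1a1 at 1.02) and 3 endothelial genes (1 up, 1 down, with Flt1 at 0.99) were tested. The list's median, mean and test differed in sign for cytokines (0.07, −0.05 and down), TGF-beta response (0.09, −0.30 and up), matrix proteases (−0.02, 0.31 and up), ribosomal proteins (−0.03, 0.06 and up) and endothelial markers (−0.22, 0.07 and up). Red cell genes (at most 3 counts in all) and acinar markers (Cela1 and Bhlha15 of 21 past the filter) were too low to test as lists, and F2r and F2rl1 alone passed it of the 4 PAR genes.

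In the knockout lines, the second comparison asks what thrombin does where PAR-1 was targeted. In edgeR's test, 0 genes passed in KO1 (888 at an unadjusted p under 0.05, lowest adjusted p = 0.806) and 0 in KO8 (1245 at an unadjusted p under 0.05, lowest adjusted p = 0.126), and DESeq2 called 0 in both. In KO8, 5 genes passed without the filter and 7 with the replicate block, with Id1, Lcn2, Clca3b and Muc5b among them each time. Of these, Lcn2, Clca3b and Muc5b were chosen after their values were seen. Id1 had a log2 fold change of 0.81 in KO1 too, where it did not pass, and went from 22.4 to 24.2 CPM in KPC. F2r had a log2 fold change near 0 in KO1 (0.021, 95% interval −0.068 to 0.11) and in KO8 (0.0035, −0.085 to 0.092). Csf2 had a log2 fold change of −0.71 (−1.46 to 0.034) in KO1 and −0.093 (−0.30 to 0.12) in KO8, and Ptgs2 0.093 (−0.43 to 0.61) and −0.058 (−0.52 to 0.40), the latter 0.53 without KO8 vehicle library 3. The SE of Ptgs2 in KO8 was 0.22 with that library and 0.077 without it. As the spread is pooled over groups, the Ptgs2 interval in KO1 does not reflect the KO1 libraries alone. The 20 genes with the largest changes in KPC, each of at least 4.70 on the log2 scale there, had log2 fold changes of at most 0.43 in KO1 and 0.44 in KO8 in absolute terms, and no 95% interval of them reached beyond 1.91 and 1.32. Without KO8 vehicle library 3, Areg, which is among them, had 0.82 in KO8. Over the 2524 genes that changed at least 2-fold in KPC, the median change in the KPC direction was 1.59 in KPC, 0.022 in KO1 and 0.030 in KO8.

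**Figure D3:**
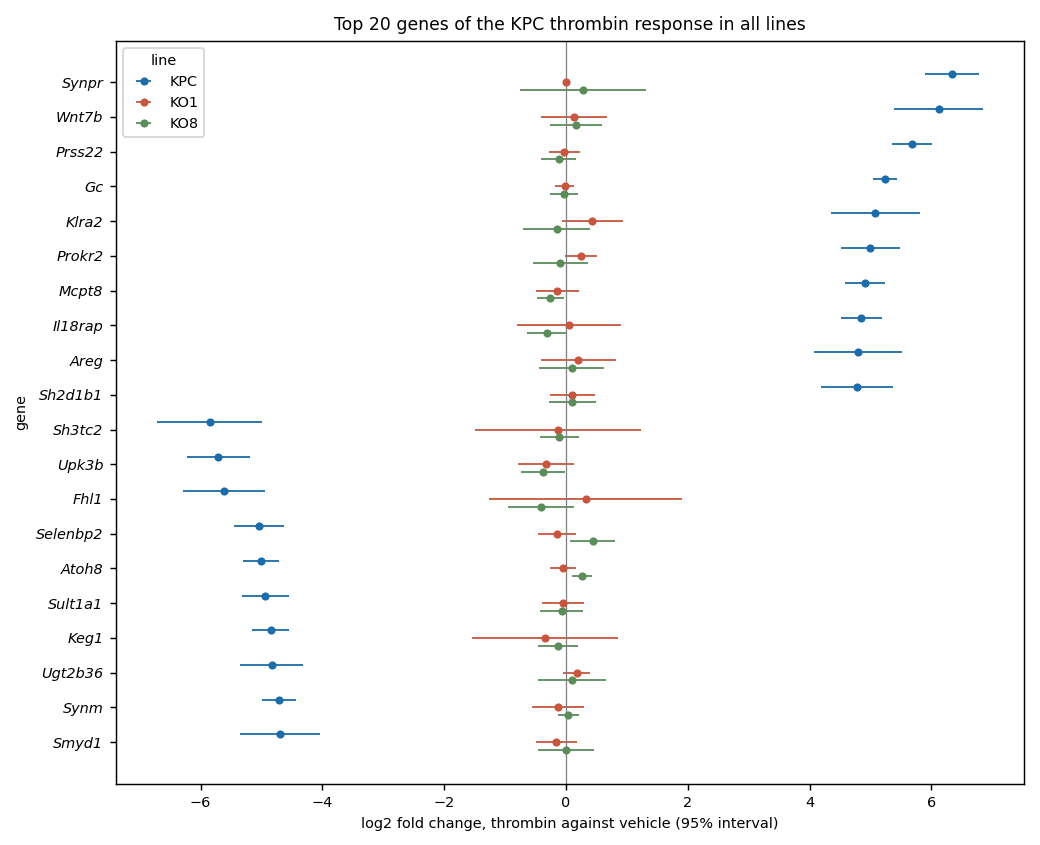
Log2 fold change with thrombin against vehicle (horizontal axis, points with 95% intervals) in KPC, KO1 and KO8 for the 20 genes with the largest changes in KPC (vertical axis). The KPC points lie at least 4.70 from 0, and those of KO1 and KO8 lie within 0.44 of 0, although Areg in KO8 is at 0.82 without KO8 vehicle library 3.

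The KO8 count rested on 1 library. Without KO8 vehicle library 3, 671 genes passed, 380 up and 291 down, 23 of them at least 2-fold. Of these, 580 were also called in KPC, 502 in the same direction and 78 in the opposite one. Of all genes tested, 68.65% were called in KPC, 49.93% of them up, so many shared calls would occur in any set of genes. Ptgs2 then had 0.53 and Areg 0.82. No list passed in KO1, but mitochondrially encoded genes passed without KO1 vehicle library 4 (camera adjusted p of 0.0301) or thrombin library 3 (0.00442), and ribosomal protein genes without thrombin library 1 (0.00326). In KO8, 6 lists passed although none of their genes did, with Id1 of the TGF-beta list passing in 2 of 8 alternatives. Immediate early genes (1.44e-06, adjusted p = 0.413 with an estimated correlation, 1 up when adjusted over the list alone), TGF-beta response genes (0.00365, adjusted p = 0.202, 3 up when adjusted over the list alone), MAP kinase targets (0.0118, adjusted p = 0.559) and p53 targets (0.0353, adjusted p = 0.559) were higher. Glycolysis and hypoxia genes (0.00475, adjusted p = 0.532) and NRF2 targets (0.0101, adjusted p = 0.0861) were lower, and so no call held with an estimated correlation. MAP kinase and p53 targets were lost without KO8 vehicle library 1 (0.21 and 0.438), vehicle library 4 (0.11 and 0.11) or thrombin library 3 (0.0705 and 0.138). Glycolysis and hypoxia genes were lost without vehicle library 4 (0.0634), and NRF2 targets without vehicle library 3 (0.0606). Other lists passed without 1 KO8 library: G2/M genes without vehicle library 1 (0.0143), 3 (2.18e-10) or 4 (0.00919), cholesterol (7.11e-10), G1/S (6.55e-05) and angiogenic genes (0.0101) without vehicle library 3, cytokine genes without vehicle library 1 (0.0143) or 4 (0.0439), junction genes without vehicle library 4 (0.0172), and mitochondrially encoded genes without thrombin library 4 (0.0479).

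Whether the thrombin effect differed between the lines was tested directly. Several of the genes with the largest changes in KPC differed most from both knockout lines. The log2 difference from KO1 and KO8 was 5.99 and 5.96 for Wnt7b, 5.71 and 5.81 for Prss22, 5.27 and 5.28 for Gc, 5.05 and 5.17 for Mcpt8, and 4.80 and 5.16 for Il18rap. On the falling side it was −5.38 and −5.33 for Upk3b, −4.95 and −5.27 for Atoh8, −5.01 and −4.93 for Ugt2b36, −4.90 and −5.48 for Selenbp2, and −4.89 and −4.87 for Sult1a1. F2r (1.63 and 1.65), Ptgs2 (2.42 and 2.57, the latter 1.98 without KO8 vehicle library 3), Csf2 (1.90 and 1.28), Kras (0.84 and 0.81) and Trp53 (0.43 and 0.42) also responded more in KPC than in KO1 and KO8. For F3 the difference was −0.13 from KO1 (adjusted p = 0.287) and −0.31 from KO8 (adjusted p = 0.0123). F2rl1 differed by 0.23 from KO8 (adjusted p = 0.00738) and by 0.17 from KO1 (adjusted p = 0.0437), but the latter call was lost in 12 of 16 fits without 1 library, with adjusted p from 0.0529 to 0.0813, and held without KPC vehicle library 4, KPC thrombin library 3, KO1 vehicle library 1 or KO1 thrombin library 3. It was also lost in 4 of 8 other alternatives, with adjusted p from 0.0736 to 0.177.

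The differences by group in these tests, which use the same KPC libraries, followed the lists named for KPC. All 23 G2/M genes responded more positively in KPC than in KO1 (camera adjusted p of 3.97e-18) and KO8 (2.81e-18), though with an estimated correlation both had adjusted p = 0.128. For the stress response list the difference held with an estimated correlation. There, 9 genes were up and 6 down of 20 against KO1 (6.24e-06, adjusted p = 0.00107 with an estimated correlation) and 10 up and 3 down against KO8 (4.29e-06, adjusted p = 0.000788, 5 down when adjusted over the list alone). Ductal markers had 2 up and 10 down of 15 against KO1 (0.00593, adjusted p = 0.085 with an estimated correlation, 11 down when adjusted over the list alone) and 2 up and 13 down against KO8 (0.00055, adjusted p = 0.0133). MAP kinase targets had 14 up and 2 down of 21 against KO1 (6.24e-06, adjusted p = 0.128 with an estimated correlation) and 15 up and 2 down against KO8 (1.68e-05, adjusted p = 0.111). Junction genes had 2 up and 11 down of 17 against KO1 (0.00111, adjusted p = 0.128) and 3 up and 10 down against KO8 (0.000233, adjusted p = 0.103, 11 down when adjusted over the list alone). Interferon genes had 16 down of 24 in both, with 0 and 1 up (0.018, adjusted p = 0.128, and 0.00425, adjusted p = 0.103). Cholesterol genes had 15 down of 22 in both (0.00585, adjusted p = 0.622, and 0.0137, adjusted p = 0.698, with 16 down against KO1 when adjusted over the list alone). Glycolysis and hypoxia genes had 14 up and 2 down of 21 in both (0.018, adjusted p = 0.395, and 0.00379, adjusted p = 0.308). G1/S genes had 15 up and 1 down of 22 against KO1 (0.018, adjusted p = 0.48) and 17 up and 0 down against KO8 (0.00997, adjusted p = 0.471), and basal subtype genes 3 up and 1 down of 5 in both (0.0165, adjusted p = 0.128, and 0.0133, adjusted p = 0.114). Angiogenic genes missed the threshold against KO8 (0.0605) but passed in 6 of 16 fits without 1 library: without KO8 vehicle library 1 (0.0458), 2 (0.0497), 3 (0.026) or 4 (0.0404), KO8 thrombin library 2 (0.0489) or KPC thrombin library 3 (0.047).

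In edgeR's test of the difference, 8619 genes passed between KPC and KO1 (4398 with the higher value in KPC, 4221 with the lower) and 8878 between KPC and KO8 (4435 and 4443). In 7775 genes the call in KPC and both differences passed with the same sign. Of the 2524 genes that changed at least 2-fold in KPC, the effect differed from that in KO1 for 2273 (90.1%) and from that in KO8 for 2391 (94.7%). These genes were chosen by their change in KPC, and the differences use the same KPC libraries. The shares, like the 7775 genes, are therefore high in part through that choice.

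Under vehicle, the third comparison asks how the knockout lines differed from KPC without added thrombin. Muc1 and Lamb3 were far lower in both lines. Muc1, an epithelial mucin, fell from 101.8 ± 2.67 CPM in KPC (SD, n = 4) to 2.90 ± 0.359 in KO1 (log2 fold change −5.13 ± 0.091, SE) and 4.01 ± 0.751 in KO8 (−4.67 ± 0.084). Lamb3, a laminin subunit of basement membranes, fell from 76.2 ± 2.46 to 1.90 ± 0.23 CPM in KO1 (−5.32 ± 0.098) and 3.38 ± 0.288 in KO8 (−4.50 ± 0.087). Serpinh1, a collagen chaperone, rose from 2.70 ± 0.335 to 261.1 ± 13.8 CPM in KO1 (6.60 ± 0.082) and 81.0 ± 6.51 in KO8 (4.91 ± 0.084), and Bcat1, which transfers amino groups of branched amino acids, rose in KO1 (7.15 ± 0.17) and KO8 (7.69 ± 0.17). As each knockout is a single line, these differences cannot be assigned to the targeting of F2r.

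Other genes higher in both knockout lines were, as log2 fold changes in KO1 and KO8, Kctd17 (7.22 and 6.74), the mitochondrial folate enzyme gene Aldh1l2 (7.49 and 6.64), the cathepsin gene Ctsf (4.93 and 5.31), Layn (4.72 and 4.71), Aebp1 (4.58 and 4.91) and Plcb4 (5.19 and 4.44). The fibrinogen chain gene Fgb had 0.0945 CPM in KPC, most of its few counts in vehicle library 3, and rose to 5.20 CPM in KO1 and 2.80 in KO8. Rab39b had no count in KPC vehicle libraries and was at least 129-fold higher in KO1 and at least 70.6-fold higher in KO8. Lower in both were Serpinb1a (−5.47 and −4.91), Gas6, a ligand of the receptor Axl (−4.62 and −5.37), the adenosine receptor gene Adora1 (−4.50 and −6.20), Fam169b, Cdyl2 and Pof1b. Mei1 was at least 521-fold lower in KO1, and its ratio was 1750 (314 to 69100) in KO8. For Sdc2, a syndecan, the ratio of KPC to the knockout line was 473 (131 to 3900) in KO1 and 352 (121 to 1710) in KO8. In KO1 the ratio was 1170 (211 to 46300) for Fam169b, 406 (112 to 3350) for Cdyl2 and 391 (70.1 to 15400) for Pof1b, and in KO8 the log2 fold changes of Fam169b and Cdyl2 were −7.89 and −6.74. Pof1b went from 4.13 CPM to 0.0497 in KO8, where most of its few counts were in vehicle library 1.

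Of the genes fixed in advance, F3 (0.99 in KO1, 0.65 in KO8), Kras (0.98 and 0.58) and Ptgs2 (1.39 and 3.09) were higher than in KPC in both lines, with Ptgs2 in KO8 at 2.49 without KO8 vehicle library 3. Csf2 was lower in KO1 (−2.50) and higher in KO8 (1.24). Trp53 was lower in KO1 (−0.42) and did not pass in KO8 (0.14, adjusted p = 0.0722), though it did in 4 of 8 alternatives, with adjusted p from 0.00321 to 0.05. In KO1, edgeR called 11950 genes against KPC (5999 up, 5951 down, 3555 at least 2-fold), and in KO8 10657 (5379 up, 5278 down, 2374 at least 2-fold).

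The stress response list was higher in both knockout lines under vehicle, and the classical subtype list was lower. Of 20 stress response genes, 16 were up and 1 down in KO1 (camera adjusted p of 0.00158, adjusted p = 0.0232 with an estimated correlation) and 17 up and 0 down in KO8 (9.28e-10, adjusted p = 2.97e-05 with an estimated correlation). Psat1 (2.42 and 2.62), Asns (2.46 and 2.43) and Atf4 (1.71 and 1.78) rose in both. Of 18 classical subtype genes, 4 were up and 11 down in KO1 (0.00503, adjusted p = 0.0415), with Gata6 at −1.03, and 3 up and 12 down in KO8 (5.43e-05, adjusted p = 0.00223), with Anxa10 at −4.06. Junction genes had 6 up and 10 down of 17 in KO1 (0.00452, lost with an estimated correlation, adjusted p = 0.195) and 3 up and 12 down in KO8 (1.42e-07, adjusted p = 0.013), with Dsp at −5.63 and −3.52 and Ocln at −2.32 and −4.54. MAP kinase targets had 13 up and 3 down of 21 in KO1 (0.00997, lost with an estimated correlation, adjusted p = 0.341) and 20 up and 0 down in KO8 (6.16e-09, adjusted p = 0.0222), with Ccnd1 at 1.26 and 1.00.

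G1/S, G2/M and glycolysis genes were also higher in both knockout lines, but no such call held with an estimated correlation. G2/M genes had 21 up of 23 in KO1 (0.00158, adjusted p = 0.594 with an estimated correlation) and 23 in KO8 (0.000116, adjusted p = 0.602), such as Tpx2 (0.92 and 0.90). G1/S genes had 18 up and 0 down of 22 in KO1 (0.00126, adjusted p = 0.313) and 16 up and 2 down in KO8 (0.0431, adjusted p = 0.602), such as Ung (1.41 and 0.73), and the latter call was lost without KO8 vehicle library 1 (0.0595), 2 (0.0621) or 4 (0.0802). Glycolysis and hypoxia genes had 16 up and 2 down of 21 in KO1 (0.00126, adjusted p = 0.195) and 16 up and 4 down in KO8 (9.33e-05, adjusted p = 0.109), such as Egln3 (2.06 and 1.92).

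Other lists past the threshold against KPC were, in KO1, interferon genes, with 3 up and 18 down of 24 (0.00356, adjusted p = 0.0809 with an estimated correlation) and Ddx58 at −2.55. Cholesterol genes had 16 up and 1 down of 22 in KO1 (0.00452, adjusted p = 0.594), with Pcsk9, which lowers the LDL receptor, at 5.17, and NRF2 targets had 11 up and 5 down of 17 (0.0139, adjusted p = 0.0694), with Slc7a11 at 2.69. Cytokine and prostaglandin genes had 5 up and 10 down of 19 in KO1 (0.0222, adjusted p = 0.341), with the chemokine gene Cxcl16 at −2.68, and 16 up and 2 down in KO8 (2.03e-05, adjusted p = 0.0691), with the chemokine gene Cxcl3 at 3.78. NF-kB targets had 4 up and 11 down of 18 in KO1 (0.0381, adjusted p = 0.559), with Vcam1 at −2.23, and coagulation genes 5 up and 5 down of 13 (0.0286, adjusted p = 0.15), with F5 at −4.48, the latter lost without KO1 vehicle library 3 (0.052) or 4 (0.0534). In KO8, ductal markers had 2 up and 10 down of 15 (6.52e-06, adjusted p = 0.00209), with Krt19 at −1.46 and Hnf1b at −1.09, and axon guidance genes 4 up and 12 down of 16 (0.0327, adjusted p = 0.0755), with Efna1 at −1.80. Endothelial markers had 2 up and 0 down of 3 (0.007, adjusted p = 0.045), which were Flt1 (1.60) and Vwf (2.13). Vwf had few counts, at 0.212 ± 0.0688 CPM in KPC and 0.964 ± 0.347 in KO8 vehicle libraries. Basal subtype genes had 5 up of 5 in KO8 (0.0425, adjusted p = 0.181), with Areg at 3.30 (2.56 without KO8 vehicle library 3), a call lost without KO8 vehicle library 1 (0.0595), 2 (0.0762) or 4 (0.0834) or KPC vehicle library 1 (0.0882), 2 (0.0835) or 4 (0.111). For the lists of the comparisons under vehicle that are named here, the counts were the same when adjusted over the list alone.

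The changes against KPC overlapped between the lines. Of the genes called in both, 3529 were higher in both and 3510 lower in both, 7039 in all, and 1705 went in opposite directions. Independent lists would share 4078 with the same sign, but changes from the same KPC vehicle state would share more even in unrelated lines. Both comparisons use the same KPC vehicle libraries, and simulated unchanged lines against those libraries gave 0 shared calls and a covariance of 0.00274, against 0.312 in the data (difference 0.309). The correlation of fold changes across 10341 genes, which are not independent replicates, was 0.545, against 0.498 in the simulation. With the KPC vehicle libraries split between the lines, it was 0.538 to 0.545, with 6172 to 6269 shared calls of the same sign. The simulation and the split address sampling error but do not remove the shared KPC vehicle state. The overlap therefore does not show that the knockout lines were alike beyond that.

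Genes of whole chromosomes were shifted together in the knockout lines. Relative to all genes, the median log2 fold change of the 458 genes on chromosome 13 was −0.67 in KO1 (95% interval −0.74 to −0.59) and −0.50 in KO8 (−0.56 to −0.43), and 85.8% and 86.0% of these genes lay below the median of all genes. In KO1, chromosome 16 (−0.50) was also lower, and chromosome X (0.61), 17 (0.36), 6 (0.36), 15 (0.33) and 9 (0.32) were higher. In KO8, chromosome 8 was lower (−0.39). Smaller shifts with intervals away from 0 included chromosomes 11 (−0.25) and 5 (0.22) in KO1 and chromosome 6 (0.22) in KO8. Between thrombin and vehicle in KPC, no chromosome was shifted by more than 0.063 in absolute terms.

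**Figure D4:**
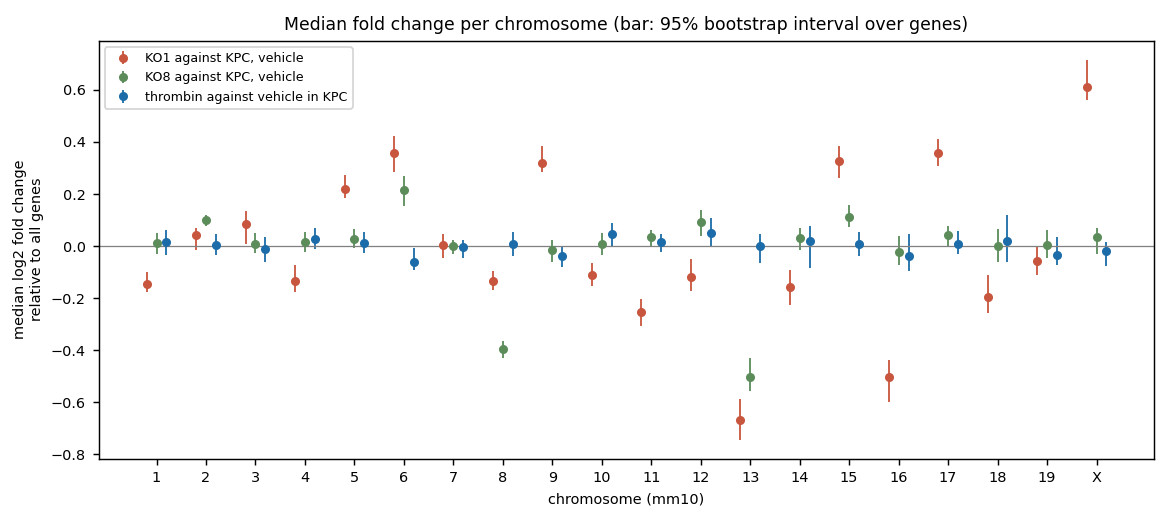
Median log2 fold change of the genes of each chromosome relative to all genes (vertical axis, points with 95% bootstrap intervals) for KO1 against KPC, KO8 against KPC and thrombin against vehicle in KPC, by chromosome (horizontal axis). Chromosome 13 stands at −0.67 in KO1 and −0.50 in KO8, while the thrombin points all lie near 0.

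Between the knockout lines, the last comparison asks how far they were alike under vehicle. Inflammatory genes were lower in KO1 than in KO8. Csf2 had 0.77 ± 0.0919 CPM in KO1 and 10.3 ± 1.78 in KO8 (SD, n = 4), a log2 fold change of −3.74 ± 0.17 (SE). The chemokine gene Ccl2 had no count in KO1 and was at least 263-fold lower than in KO8, and coagulation factor V, F5, was also lower in KO1 (−6.41 ± 0.053). Ptgs2 was lower in KO1 (−1.69 ± 0.24), with 132.0 ± 89.7 CPM in KO8, where library 3 stood apart at 265.7, and the log2 fold change was −1.10 without it.

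Of 19 cytokine, chemokine and prostaglandin genes, 17 were lower in KO1 than in KO8 and 1 was higher (camera adjusted p of 9.67e-12, adjusted p = 0.0104 with an estimated correlation), among them Cxcl5 (−2.02), Csf1 (−2.22) and Il33 (−1.75). Of 24 interferon genes, 18 were lower and 6 higher (0.000161, adjusted p = 0.0104), with Oasl2 at −3.54 and Gbp2 at −3.35. Of 17 NRF2 targets, 11 were higher and 3 lower (0.00133, adjusted p = 0.0104), with Ugdh (1.09), Me1 (1.19) and Gsta4 (1.23). These 3 calls held with an estimated correlation, and the next 7 did not. Cholesterol genes were higher, 20 up and 1 down of 22 (0.00101, adjusted p = 0.506), such as Nsdhl (1.54) and Mvd (1.38), as were G1/S genes, 16 up and 2 down of 22 (0.0308, adjusted p = 0.506), such as Rrm2 (1.12), and axon guidance genes, 9 up and 4 down of 16 (0.0308, adjusted p = 0.0837), such as Ntn4 (1.62). Antigen presentation genes were lower, 1 up and 9 down of 12 (0.00998, adjusted p = 0.0683), such as H2-Q4 (−4.20), as were NF-kB targets, 4 up and 13 down of 18 (0.0195, adjusted p = 0.474), such as Ccl20 (−3.05). TGF-beta response genes were lower, 5 up and 10 down of 20 (0.044, adjusted p = 0.224), a call lost without KO1 vehicle library 1 (0.0553) or 2 (0.0535) or KO8 vehicle library 3 (0.0515). Endothelial markers were lower, 0 up and 2 down of 3 (0.0194, adjusted p = 0.0828), lost without KO1 vehicle library 1 (0.0553), 3 (0.0595) or 4 (0.062) or KO8 vehicle library 1 (0.0557) or 4 (0.0566). MAP kinase targets passed without KO8 vehicle library 1 (0.0496) and coagulation genes without KO8 vehicle library 3 (0.0493).

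Several genes were present in 1 knockout line and nearly absent in the other. Higher in KO1 were Tmem150c (7.82), Sdr39u1 (at least 414-fold), Manea (ratio 851, 236 to 7030), H2-Q10 (179, 49.7 to 1480) and Cdh23 (217, 38.9 to 8570). Lower in KO1, beside Ccl2, were the retinoic acid receptor gene Rarb (at least 409-fold) and, with the ratio of KO8 to KO1, the transcription factor gene Foxg1 (1950, 351 to 77100), Nectin3 (1790, 321 to 70600) and the mannosidase gene Man1a (1530, 275 to 60600). F2r (0.34), F3 (0.33) and Kras (0.40) were higher and Trp53 (−0.56) lower in KO1. edgeR called 11115 genes, 5602 up and 5513 down in KO1, with 2640 changed at least 2-fold. The root mean square distance between groups in log2 CPM was 0.734 between KO1 and KO8, 0.858 between KO1 and KPC and 0.644 between KO8 and KPC, all under vehicle.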

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

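Of the tests in this part, the one on immediate early genes, the thinning of the libraries, the test of KO8 vehicle library 3 alone and the splits without it were chosen after the result was seen. In 406 groups of 4 libraries, the highest or lowest library was compared with the nearest of the others, and in 37 groups it stood apart. Chance alone marks about 1 in 20 groups, 20.3 here, so most single cases below carry little weight. That rate does not hold for genes near 0 CPM, such as Foxg1, Nectin3 and Man1a in KO1, where 1 read sets a library apart. Such cases carry no weight.

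KO8 vehicle library 3 stood apart most often. It had 20700 genes with a count, Ptgs2 at 265.7 CPM, Bcat1 at 91.4, Aldh1l2 at 59.8, Manea at 0.066 and Cdh23 at 0.033, and Sdc2 at 0 CPM. Its mean log2 CPM was apart for coagulation (4.71), SRF target (7.34), G1/S (5.59) and cholesterol genes (6.58). Other KO8 libraries apart were vehicle 1 for ribosomal proteins (mean log2 CPM 5.91) and for Mei1 (0.040 CPM), vehicle 4 for junction genes (mean log2 CPM 4.14) and thrombin 4 for F2rl1 (76.4 CPM).

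In KO1, vehicle library 1 was apart for antigen presentation (mean log2 CPM 2.65) and stress response genes (6.57) and, in CPM, for F2rl1 (67.0), Gas6 (0.637), Foxg1 (0.049) and Nectin3 (0.049). Vehicle library 4 was apart for MAP kinase targets (mean log2 CPM 5.70), matrix proteases (4.86) and classical subtype genes (3.28) and for Pof1b (0.042 CPM). Vehicle library 2 was apart for mitochondrially encoded genes (mean log2 CPM 7.20), vehicle library 3 for Man1a and Fam169b (0.043 CPM each) and thrombin library 3 for cholesterol genes (mean log2 CPM 7.47). In KPC, vehicle library 2 was apart for Ptgs2 (15.0 CPM), Prss22 (0.582) and Serpinb1a (9.13), vehicle library 3 for Selenbp2 (5.41 CPM) and Ctsf (0.349), vehicle library 1 for SRF targets (mean log2 CPM 7.38) and thrombin library 3 for G1/S (5.76) and mitochondrially encoded genes (7.01).

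The first pattern weighed is that thrombin calls in KO8 appeared without vehicle library 3, with 671 genes against 0. Greater depth of that library was argued against, since thinning all libraries to 16219715 counts left 0 genes called with it and 490 without it. Tested alone, with its spread assumed to be that of the other groups, it differed from the 4 KO8 thrombin libraries at 448 genes (each of those from the other 3 at 0 or 1) and from the other 3 vehicle libraries at 2164, so a thrombin library under its label is argued against as the whole cause, but a wrong label together with another disturbance stays open. Another candidate explanation that stays open is a burst of immediate early genes in that dish: the list's median deviation from the other vehicle libraries, 0.32, lay at percentile 100 of random lists matched on expression, with Junb at 57.6 against 24.5 CPM, but it was neither the only nor the largest shift, since cytokine genes (0.28) were also at percentile 100 and G2/M (−0.60) and cholesterol genes (−0.40) at percentile 0. What set off that state was not tested, nor was any biological explanation from the design.

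The thrombin effect differed between KPC and KO1 at 8619 genes and between KPC and KO8 at 8878, and 10 gene lists passed in each test. With an estimated correlation, 1 and 2 of them held, and the others had adjusted p from 0.085 to 0.622 against KO1 and from 0.103 to 0.698 against KO8. As log2 differences from KO1 and KO8, the values were 1.63 and 1.65 for F2r, 0.17 (a call lost in 12 of 16 fits without 1 library, adjusted p from 0.0529 to 0.0813, and in 4 of 8 other alternatives) and 0.23 for F2rl1, 0.84 and 0.81 for Kras, 0.43 and 0.42 for Trp53, 1.90 and 1.28 for Csf2, and 2.42 and 2.57 for Ptgs2 (the latter 1.98 without KO8 vehicle library 3). F3 differed from KO8 (−0.31). The rising genes were Wnt7b (5.99 and 5.96), Prss22 (5.71 and 5.81), Gc (5.27 and 5.28), Mcpt8 (5.05 and 5.17) and Il18rap (4.80 and 5.16). The falling genes were Upk3b (−5.38 and −5.33), Atoh8 (−4.95 and −5.27), Ugt2b36 (−5.01 and −4.93), Selenbp2 (−4.90 and −5.48) and Sult1a1 (−4.89 and −4.87).

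Other splits of the same libraries set the counts against chance. For thrombin in KPC, the real split, 1 of 35, gave 10719 genes and the highest other gave 0, which argues against chance as far as 35 splits can. The same holds for KO1 against KPC (11950 genes, highest other 0), KO8 against KPC (10657, highest other 196) and KO1 against KO8 (11115, highest other 1090), again with 1 of 35 splits as large. Splits that mix unlike groups widen the spread within each and so call few genes. None of these splits bears on handling shared by a whole group. For thrombin in KO1 (highest other 8) and KO8 (highest other 1552) the real count was 0, which all 35 splits reach by construction, so these splits say nothing about chance. The highest in KO8 parts vehicle libraries 1, 2 and 4 and thrombin library 1 from the rest. So many calls point to a structure of the samples, with vehicle library 3 beside thrombin libraries. Without that library, left out because it stood apart, 1 of 35 splits, the real one, gave 671 genes and the highest other gave 408, but that library was chosen after its effect on the count was seen, so these splits do not exclude chance. For the differences, 4 of 100 draws gave as many genes, the real one included, both for KO1 (8619, highest other 8861) and for KO8 (8878, highest other 9056). The 3 other draws kept the KPC groups whole and regrouped only knockout libraries, and draws that mixed the KPC groups gave 0. These draws therefore repeat the result of the KPC splits and say nothing about the grouping of the knockout libraries.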

How the results depend on the processing

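Of the alternatives here, only the thinning was chosen after seeing the data. Over the alternatives and the fits without 1 library, results for single named genes kept direction and side of the threshold in 17031 cases, 37 gained a call, 30 lost it and 1 reversed. For single lists the figures were 3027 kept, 110 gained and 87 lost. Thrombin in KO8 gave 0 genes, but 5 without the filter (1 of them at least 2-fold), 7 with the replicate block and 0 to 671 (0 to 23 at least 2-fold) in fits without 1 library, where vehicle library 3 gave the highest. The genes without the filter, chosen after their values were seen, were Id1 (0.81), Gm15710 (1.60), Lcn2 (−0.43), Clca3b (−0.29) and Muc5b (−0.29). Ptgs2 in KO8 reversed without vehicle library 3, from −0.058 to 0.53, and ran from −0.25 to 0.53 over the fits without 1 library. Without 1 library, 0 to 1 lists passed in KO1. Camera with an estimated correlation and fry passed, in that order, 2 and 29 of 31 lists for thrombin in KPC (10 with camera), 0 and 1 in KO8 (6, and the 1 was NRF2 targets), 1 and 22 for the difference from KO1 (10), 2 and 27 for that from KO8 (10), 2 and 27 for KO1 against KPC (13), 6 and 24 for KO8 against KPC (12), and 3 and 23 for KO1 against KO8 (10). The fry test does not compare a list with other genes, which its construction shows, and for the other changes the cause was not tested. All other counts of genes and lists stayed within 1.5 times, with KPC thrombin at 10314 to 10573 in fits without 1 library. Scaling by total counts, RLE or TMM moved the median of all genes by at most 0.067, and the share of higher genes in KPC was 49.9% (TMM), 47.7% (RLE) and 44.7% (total counts). Replicate numbers did not pair the samples by the rule used, a correlation over 0.1 in every pair: same-numbered libraries correlated at a mean of 0.038 in their deviations from the group means, with a highest value of 0.249, against −0.013 for others. That 17 of 24 libraries were closest to their own number is a hint of shared handling from the data, not the design. The replicate block changed no count of calls by over 1.5 times but that of thrombin in KO8. Depth limits genes of few counts, such as F2rl2 and F2rl3, and single libraries allowed 0.1 to 0.185 CPM where no read was counted.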

Other observations

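Of the tests in this part, those on chromosome copy number and on another subclone and the slope without KO8 vehicle library 3 were chosen after the result was seen, and the test of a residual response was widened from 1 to 4 gene sets after a first run.

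The genes that thrombin moved in KPC were often moved the same way in the untreated knockout lines. Areg rose by 4.80 with thrombin in KPC and was higher under vehicle in KO1 (2.80) and KO8 (3.30, or 2.56 without KO8 vehicle library 3) than in KPC, as were Wnt7b (6.12 with thrombin, then 4.18 and 4.64), the AP-1 gene Fosl1 (3.35, then 2.93 and 2.48), the cystine transporter gene Slc7a11 (2.71, then 2.69 and 3.18) and Chac1, which degrades glutathione (4.06, then 2.87 and 3.47). The growth arrest gene Gas6 (−3.21, then −4.62 and −5.37) and the desmosome gene Dsp (−2.27, then −5.63 and −3.52) were lower in all 3 comparisons. Some genes did not follow. Twist1, a mesenchymal transcription factor, had 0.16 with thrombin in KPC (adjusted p = 0.506) and was higher in KO1 (3.52) and KO8 (2.71), Pcsk9 had 0.19 (adjusted p = 0.352) and was higher in both (5.17 and 4.29), and Insig1, which restrains cholesterol synthesis, fell in KPC (−1.16) and was higher in KO1 (0.23). These examples were chosen after their values were seen.

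As a whole, 3246 genes were up and 3343 down both with thrombin in KPC and in KO1 against KPC, and 2127 went in opposite directions, where independent lists would share 4102 with the same sign. For KO8 the figures were 3379, 3340 and 1408, with 3658 from independent lists. Both changes are measured against the same KPC vehicle libraries. Separate sets of these gave correlations of 0.4255 to 0.436 for KO1 and 0.509 to 0.521 for KO8 across genes, which are not independent replicates. This argues against sampling error in those libraries as the cause. Separate sets still share the KPC vehicle state, from which even unrelated changes would correlate, so neither they nor independent lists can decide whether the changes are alike. The root mean square distance in log2 CPM to KO1 and KO8 under vehicle was 0.821 and 0.641 from KPC thrombin, against 0.858 and 0.644 from KPC vehicle. The covariance was 0.257 for KO1 and 0.229 for KO8, above the simulated values by 0.254 and 0.226. The correlation with all KPC vehicle libraries was 0.435 for KO1 and 0.521 for KO8, against 0.498 in the simulation. The simulated groups were unchanged, so groups with any change can exceed their covariance, and the excess does not show that the changes are alike. Another subclone in the KPC dishes with chromosome shifts like those of the knockout lines is argued against as well, since no chromosome shifted by more than 0.0626 between thrombin and vehicle. A subclone without such shifts would not be seen this way and stays open. A biological link stays a hypothesis that these data cannot settle, with 1 line per knockout.

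The shifts of whole chromosomes in the knockout lines may reflect chromosome copy number. At least 80.6% of chromosome 13 genes lay below the median of all genes in both lines and in the lower and the upper part of expression, and windows of 20 Mb along it ran from −0.86 to −0.48 in KO1 and from −0.60 to −0.37 in KO8. Gene length and GC content are argued against, since the shift nearer 0 was −0.51 after adjustment for them. F2r lies on chromosome 13, so part of its lower RNA in KO8, and part or all of it in KO1, may come with the chromosome. The 69 genes of its 20 Mb window had a median of −0.572 in KO1 and −0.459 in KO8 relative to all genes. F2r was lower by about as much in KO1 and by more in KO8. F2rl1, in the same window, did not pass in either line, so not every gene there followed the shift. RNA counts do not measure DNA copies, and no biological explanation from the design was tested.

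A small thrombin response left in the knockout lines was tested as the slope of their changes on those of KPC. In KO1 the slope was 0.014 over the genes called in KPC (0.012 to 0.023 over the 4 gene sets), and 1 of 35 splits, the real one, was as large, with a highest other of 0.012. A residual response of about 1.42% of that in KPC is thus a candidate explanation for KO1, where no single gene passed. In KO8 the slope was 0.022, and 13 of 35 splits were as large, the highest other at 0.049. The KO8 slope was larger than that of KO1, but its splits spread more widely. This test therefore cannot decide whether a residual response was left in KO8. Without vehicle library 3 the slope was 0.043, but that library was left out after its effect on the calls was seen, so this is no evidence for such a response.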
